A study of Mus musculus with 4 samples.

How the data were processed

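Liver RNA of 4 Wrn mutant mice given vitamin C was labelled with Cy5 and that of 4 wild-type mice with Cy3, per the labels, and each pair was hybridised to 1 array. Spot intensity values were extracted with Agilent Feature Extraction 10.5.1.1 on a whole mouse genome design annotated against mm9, per the file headers. The deposited scanner files hold, for each spot, the median intensity and median local background intensity of both channels as scanned, processed signals, and Agilent's log10 ratio of the processed red over green signal. The processed signals were background-subtracted and dye-normalized by the scanner software, per the file headers. The authors' deposited table of the series gives a log2 ratio per array, the mean log2 ratio, a p-value and adjusted p-value, and, as scores, the moderated statistic, log odds and signed fold change for 43379 spots. limma is named in the submitters' processing notes with no version. Set against the scanner values, the authors' log2 ratios matched background subtraction and loess with a slope of 1.00 and r of at least 0.999 on each array across probes, which are not independent replicates. Their median was between 0.00 and 0.01 on the 4 arrays. Per the authors' deposited table, an adjusted p under 0.05 was reached by 4283 spots, and 281 had a p under 0.001 with a change of 1.5-fold or more. That table was used for the annotation and as an alternative, and 0 of its numeric columns were left aside.

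The values here were computed from the median intensities. The design fixed before the data were examined named mean foreground intensities, which the files used here do not hold, so medians took their place. Background was corrected with normexp and an offset of 50, and ratios were normalized within arrays by loess with control spots at weight 0, in R 4.3.3 with limma 3.58.1. Control spots and spots with an outlier flag in either channel were then removed, and spots of the same probe were averaged. Of 41174 probes, 39080 were kept because they were well above background in Cy5 on at least 3 arrays or in Cy3 on at least 3 arrays, and a value was needed on 3 arrays. Probes were named by transcript accession (67.2%), a symbol in the reference (13.6%), an older symbol in the reference (1.10%) or the deposited symbol alone (3.13%), and 15.0% had no name. The reference was a RefSeq gene table of assembly GRCm38.p6, of which no coordinates are given because the array annotation used mm9. A first fit named probes by accession only and gave 3222 changed genes and 195 at 1.5-fold or more. After its counts had been seen, older symbols were added to the naming, because probes with 1 deposited symbol, such as both probes of Agxt2l1 (now Etnppl), had been split between 2 names. This gave 3189 and 193, and moved Etnppl out of the largest decreases. The brightest probe by mean intensity stood for a gene, and probes without a symbol were tested as themselves.

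The mean log2 ratio of the 4 arrays was tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment over 26114 genes. Levels per channel were taken after loess and Aquantile normalization and are open to dye bias. All 4 arrays lay on 1 slide with 1 scan time. Across tested genes, which are not independent, the log2 ratios of array pairs correlated with r from 0.376 to 0.573. On simulated arrays with 200 changed genes among 26114, the comparison recovered 2% of changes of 1.15-fold, 42% of 1.32-fold, 80% of 1.5-fold and 88% of 2-fold, and 3.64% of its calls were false. The simulated noise was independent between genes and held no dye bias of single probes. These rates therefore need not hold for the calls on the real arrays.

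The 26 pathway and 13 cell type marker lists, the alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment within each family, and 107 missing values were filled with the gene's mean. With a correlation estimated per list, 0 of the 7 pathway calls held. The text names Wrn, Gulo, Slc23a1, Slc23a2 and Nnt, the 12 largest increases and 12 largest decreases past an adjusted p of 0.05 with 1 sign on all arrays and an official symbol, and, per list, up to 2 members past the threshold in each direction or otherwise the 2 of smallest p, given as values. Some genes that this rule selects are not reported here, and none took their place. Genes named outside this rule were chosen after their values were seen. Alternatives covered background, normalization, filter, probe rule, moderation, array weights, the pairing of channels within arrays, thresholds, the authors' values and leaving out each array. Probes of closely related genes, such as those of the Saa and Cyp2b families, can cross-hybridise.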

Results

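RNA from the liver of 4 male Wrn mutant mice, 3 months old and given 0.4% vitamin C in the drinking water from weaning, was compared with liver RNA of 4 untreated wild-type males on 4 two-colour Agilent whole mouse genome arrays. Wrn encodes a RecQ-type DNA helicase. Each array carried 1 mutant animal in Cy5 and 1 wild-type animal in Cy3, and the labels describe the 4 arrays as independent biological replicates. No array had the dyes swapped, and neither untreated mutants nor treated wild-type animals were analysed here, so genotype, vitamin C and dye changed together in every ratio. Of the non-control probes, 82.5%, 95.6%, 94.4% and 95.2% were well above background in the mutant channel of arrays 1, 2, 3 and 4. The wild-type channel gave 84.2%, 96.0%, 95.0% and 96.1%. The number of arrays limits the precision of every value. All log2 ratios are mutant over wild type, with the SD over the 4 arrays.

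The comparison asked which liver transcripts differ between vitamin C-treated Wrn mutants and wild-type mice. The serum amyloid A genes, which encode acute phase proteins, had the largest decreases: Saa3 fell by 2.65 on the log2 scale (SD 1.30, n = 4), Saa1 fell by 2.48 (SD 1.32) and Saa2 fell by 2.40 (SD 1.32). The largest increases were in Cnot7, a subunit of the CCR4-NOT deadenylase, at 1.59 ± 0.16 (SD, n = 4), and in Cyp26a1, which degrades retinoic acid, at 1.56 ± 1.17. The Cyp26a1 ratio on array 3 was 0.04, and its call was lost in 12 of 19 alternatives, with an adjusted p of up to 0.249. The lipogenic enzymes Scd1 and Fasn rose by 1.30 ± 0.60 and 1.26 ± 0.79. In all, 3189 of 26114 genes passed the limma test at an adjusted p under 0.05, of which 1734 were higher and 1455 lower in the mutant. Most differences were small, with a median of 1.20-fold, and 193 genes changed by 1.5-fold or more, 95 higher and 98 lower.

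The other genes among the 12 largest increases were Gsta2 at 1.53 ± 0.51, Aqp8 at 1.49 ± 0.25, Cyp2b9 at 1.47 ± 0.63, Cfd at 1.40 ± 0.52, Hamp2 at 1.37 ± 0.41 and Gadd45g at 1.35 ± 0.43 (SD, n = 4). Lrtm1 at 1.25 ± 0.32 and Hhex, a homeobox transcription factor, at 1.24 ± 0.48 completed them. Gsta2 is a glutathione transferase, Aqp8 a water channel, and Hamp2 a relative of hepcidin. The other genes among the 12 largest decreases were Fgl1 at -1.78 ± 0.78, Slc7a2 at -1.45 ± 0.28, Dusp1 at -1.32 ± 0.28, Bach2 at -1.32 ± 0.35 and Socs2 at -1.30 ± 0.82. Slc25a30 at -1.28 ± 0.52, Saraf at -1.27 ± 0.08, Angptl8 at -1.21 ± 0.56 and Osgin1 at -1.13 ± 0.19 followed. Slc7a2 transports cationic amino acids, Dusp1 is a phosphatase of MAP kinases, and Saraf regulates store-operated calcium entry. The adjusted p of these 24 genes ran from 0.0011 for Saraf to 0.0497 for Cyp26a1. The naming rule itself required a pass and 1 sign on all 4 arrays. Without replicate 2, 17 of the 24 calls were lost, and with the pairing of channels not modelled 20 were. Of the 24 genes 10 had another kept probe, and in 7 every such probe passed in the same direction. The exceptions were Cnot7, with a second probe at 0.11 ± 0.04, Cyp2b9, at 0.09 ± 0.10, and Fgl1, at 0.33 ± 0.04, the opposite sign. With the mean of a gene's probes Cnot7 was at 0.85, Cyp2b9 at 0.78 and Fgl1 at -0.73. Probes also disagreed for Etnppl, known in the deposited annotation as Agxt2l1: the brighter probe, which stands for the gene, gave 0.57 ± 0.17, whereas on the dimmer probe the ratio was negative on all 4 arrays.

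**Figure D1:**
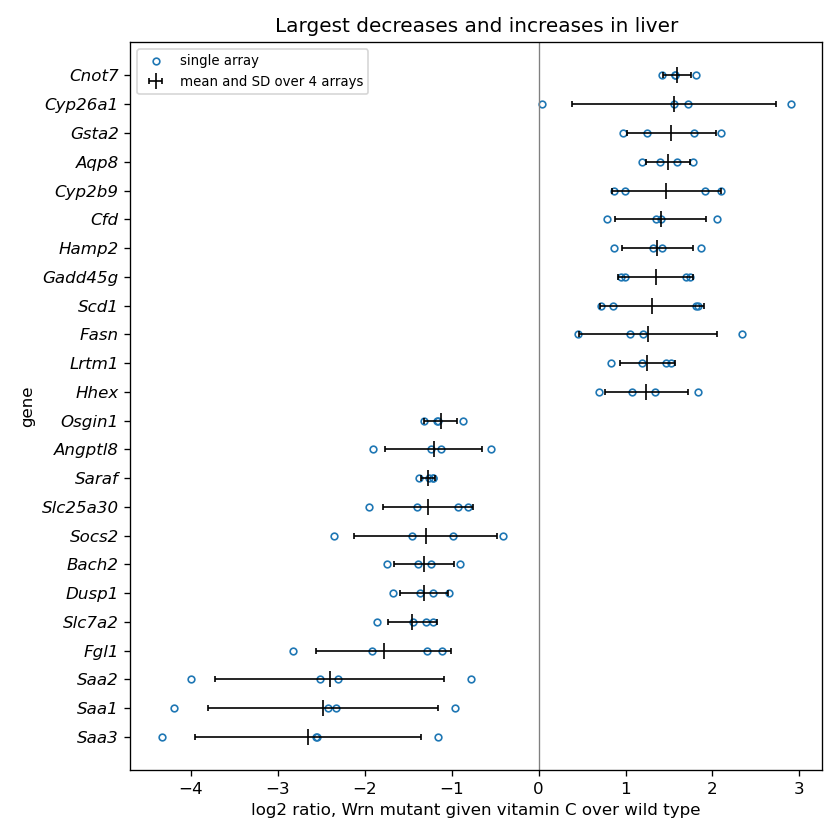
Log2 ratio of the mutant given vitamin C over wild type (x axis) for the 12 genes with the largest increase and the 12 with the largest decrease (y axis); circles are single arrays, and ticks with bars are the mean and SD of 4 arrays. The Saa genes spread widely, with an SD of 1.30 for Saa3, whereas Saraf, with an SD of 0.08, was nearly the same on all arrays.

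The count of changed genes depended on every array: without replicate 1, 2, 3 or 4 it was 507, 49, 1340 and 462, and the count at 1.5-fold or more was 152, 44, 205 and 131. With median centring in place of loess, 3416 genes were higher and 1507 lower, a share of 69.4% higher against 54.4%, and at 1.5-fold or more the split was 401 to 79, and Agilent's processed signals gave 811 changed genes.

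Probes of 1 gene often differed. Of the 96 named genes past the threshold, 42 had another kept probe; in 27 of them none of the others passed in the same direction, and in 3, Fgl1, Pkhd1 and Rbpms, 1 passed in the opposite direction. With the mean of a gene's probes 14 of the 42 calls were lost: Atp5b, Clec4g, Col3a1, Cyp1a2, Ecm1, Gadd45b, Gsr, Hnf4a, Pkhd1, Purg, Rbpms, Rps18, Sox9 and Tmlhe. Other ratios moved by over 1.5 times but kept their call, with Socs2 at -0.85, Gstm1 at 0.51, Serpinc1 at 0.26, and Gclm, Insr, Kdm3a and Tef between -0.23 and -0.22.

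The targeted gene gave no check of the labels. The probe that stands for Wrn had a log2 ratio of 0.00 ± 0.02 (SD, n = 4; adjusted p = 0.987), and where the probes lie relative to the altered part of the gene is not given in the sources used here. Among the other Wrn probes, 1 gave 0.41 ± 0.10 and passed (limma adjusted p = 0.0113 over all probes), 1 gave -0.07 ± 0.06 (adjusted p = 0.346), and 1 was not well above background. The mean of the Wrn probes was 0.12 (adjusted p = 0.0907). Gulo, the last enzyme of vitamin C synthesis in mice, had a log2 ratio of -0.20 ± 0.14 with an adjusted p of 0.0731, and its second probe gave -0.49 ± 0.08 and passed (adjusted p = 0.00777 over all probes). With the mean of both probes Gulo was lower, at -0.35 (adjusted p = 0.0165). Of the sodium-dependent vitamin C transporters, Slc23a2 was lower at -0.39 ± 0.14 (adjusted p = 0.0192) and Slc23a1 at -0.23 ± 0.10 (adjusted p = 0.0377). Nnt, a mitochondrial transhydrogenase, had a log2 ratio of -0.19 ± 0.14 (adjusted p = 0.0855), and its other probes gave 0.02 ± 0.24 and -0.05 ± 0.21. With median centring the ratio of Gulo turned to 0.26. Neither transporter passed without replicate 1, 2 or 4, when 0 of these 5 genes were past the threshold.

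In the fatty acid and triglyceride synthesis list 8 of 20 members were higher, 0 were lower and 12 did not pass, with 8 higher when adjusted over the list alone. The list was higher with camera's preset correlation (camera adjusted p = 0.000832; adjusted p = 0.791 with an estimated correlation). Scd1 and Fasn led them. In the oxidative phosphorylation list 6 of 25 members were higher, 1 lower and 18 not past the test, and adjusted over the list alone 10 were higher and 1 lower (camera adjusted p = 0.00476; adjusted p = 0.791 with an estimated correlation). Cox6c rose by 0.44 ± 0.07. Atp5b was at 0.51 ± 0.15 on its brightest probe, but its 3 other probes gave -0.06, 0.01 and -0.02, and their mean with it was 0.11 (adjusted p = 0.148). The complex I subunit Ndufv1 was lower at -0.26 ± 0.07, which turned to 0.13 with median centring. In the amino acid and urea cycle list 4 of 23 members were higher, 0 lower and 19 not past the test, and 5 were higher when adjusted over the list alone (camera adjusted p = 0.0209; adjusted p = 0.791 with an estimated correlation). Gnmt, a glycine methyltransferase, rose by 0.76 ± 0.23 and Bhmt, a betaine-homocysteine methyltransferase, by 0.66 ± 0.41. The oxidative phosphorylation list had an adjusted p of 0.112 without replicate 4 and 0.0971 with Agilent's processed signals, and the amino acid list 0.0857 and 0.197. Median centring in place of loess gave the higher lists far smaller values. Camera's adjusted p was then 5.03e-10 for oxidative phosphorylation, 2.39e-09 for the amino acid list and 1.55e-05 for the fatty acid list. Whether a dye trend left after loess adds to these lists was not tested. With the mean of a gene's probes 5 fatty acid and 3 oxidative phosphorylation genes were higher.

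In the extracellular matrix and fibrosis list 7 of 24 members were lower, 0 higher and 17 not past the test, and adjusted over the list alone 9 were lower and 1 higher (camera adjusted p = 0.000134; adjusted p = 0.791 with an estimated correlation). Sparc was lower at -0.56 ± 0.16. The collagen gene Col3a1 was at -0.51 ± 0.15 on its brightest probe and at 0.09 and 0.01 on the others, with a mean of -0.14 (adjusted p = 0.0872). With the mean of a gene's probes 3 members of the list were lower. Of 25 endoplasmic reticulum stress genes 7 were lower, 0 higher and 18 not past the test, with 9 lower when adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.791 with an estimated correlation). With the mean of a gene's probes 4 were lower. Xbp1, a transcription factor of the unfolded protein response, was at -0.72 ± 0.13, and the chaperone Calr at -0.56 ± 0.19. In the complement and coagulation list 10 of 25 members were lower, 2 higher and 13 not past the test; adjusted over the list alone, 10 were lower and 3 higher (camera adjusted p = 0.0350; adjusted p = 0.791 with an estimated correlation). C6 was lower at -0.92 ± 0.39 and C2 at -0.61 ± 0.25, whereas F2, the gene of prothrombin, was higher at 0.53 ± 0.16 and Serpinc1, the gene of antithrombin, at 0.53 ± 0.10. The endoplasmic reticulum list was not past the threshold with median centring (adjusted p = 0.834), and the complement list turned upward there (adjusted p = 0.104). The complement list was also lost without background correction (adjusted p = 0.0511) and without replicate 2 (0.0689) or 4 (0.249).

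The acute phase and inflammation list was lower as a set (camera adjusted p = 0.00327; adjusted p = 0.791 with an estimated correlation). Of its 26 members 5 were lower, 1 was higher and 20 did not pass; adjusted over the list alone, 7 were lower and 1 higher. The higher gene was the chemokine Ccl2, at 0.36 ± 0.11. The list had an adjusted p of 0.0513 without replicate 4 and 0.145 with median centring. The spread lay mainly in the wild-type animals: the log2 intensity of Saa1 ran over 4.34 units among the 4 wild-type channels and over 1.60 units among the 4 mutant channels. On array 4 the wild-type channel also had the highest level of Lcn2, at 15.5 against 8.80, 9.27 and 8.96 on the other arrays. The mutant channel of array 4 was likewise above the other mutants, at 12.3 against 8.45, 8.44 and 8.84 for Lcn2 and at 14.2 against 11.8, 11.3 and 12.5 for Saa3.

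**Figure D2:**
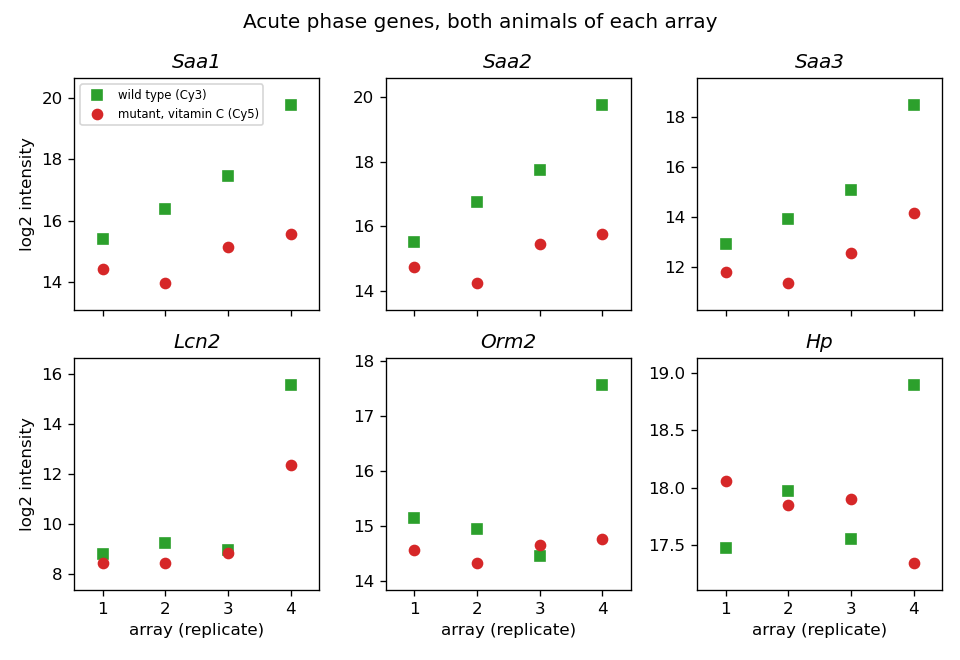
Log2 intensity after loess and Aquantile normalization (y axis, own scale per gene) of 6 acute phase genes on each array (x axis), with squares for the wild-type and circles for the mutant animal. On array 4 the wild-type animal stands above the other animals, with Saa1 at 19.8 against 15.6 in the mutant of that array, and for Saa3 and Lcn2 the mutant of array 4 stands above the other mutants.

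The remaining pathway lists did not pass camera, the lowest adjusted p among them being 0.210. The antioxidant and glutathione list had 8 of 29 members higher and 2 lower (11 and 5 adjusted over the list alone), with Gsta2 and the glutathione transferase Gstm1 at 0.94 ± 0.36 among the higher and the glutathione synthesis subunit Gclm at -0.45 ± 0.17 and the glutathione reductase Gsr at -0.35 ± 0.17 lower. Its camera adjusted p was 0.210. In the vitamin C list 2 of 12 members were higher, Gstm1 and Rgn (0.42 ± 0.20), and 2 were lower, both transporters; 2 and 3 passed adjusted over the list alone, and 2 and 3 with the mean of a gene's probes. Of 17 dioxygenases that use vitamin C, 1 was higher, Tmlhe at 0.23 ± 0.12, and 2 were lower, Kdm3a at -0.41 ± 0.02 and Plod2 at -0.22 ± 0.05; adjusted over the list alone there were 2 and 2. Of 15 measured genes flanking Wrn, 1 was higher, Purg at 0.20 ± 0.08, and 4 were lower, among them Saraf and Rbpms at -0.50 ± 0.10 (2 and 4 adjusted over the list alone). The other Rbpms probes gave 0.24 ± 0.11 (adjusted p = 0.0342 over all probes) and 0.13 ± 0.06, and the mean of its probes was -0.04. Recql4, another RecQ helicase, was the 1 higher gene of the 11 RecQ and telomere genes, at 0.24 ± 0.08, also adjusted over the list alone.

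**Figure D3:**
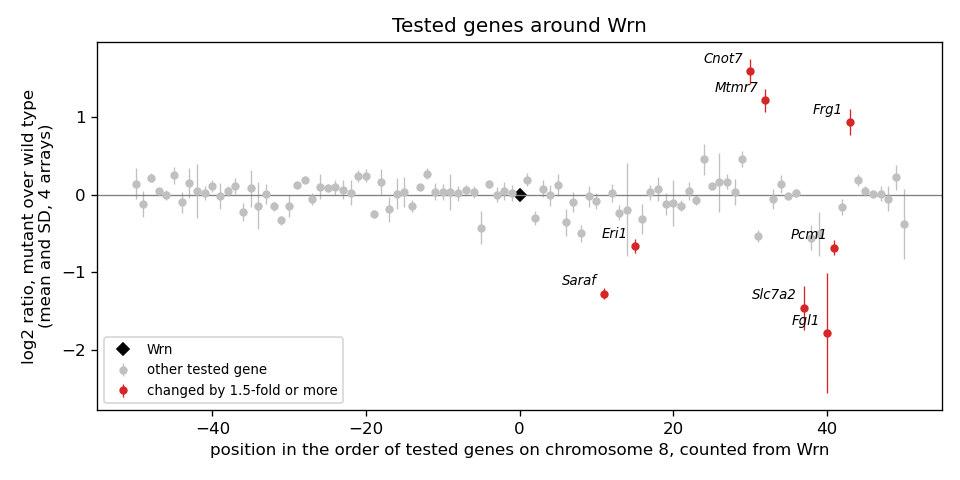
Mean log2 ratio and SD over 4 arrays (y axis) of the 100 tested genes nearest to Wrn, in their order on chromosome 8 (x axis, number of tested genes from Wrn); the diamond is Wrn, and the named points are genes changed by 1.5-fold or more. The 8 such genes, from Saraf to Frg1, lie on 1 side of Wrn and go both ways, from -1.78 for Fgl1 to 1.59 for Cnot7.

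Of 26 PPAR alpha targets 3 were higher and 3 lower (4 and 3 adjusted over the list alone), with Fabp1 at 0.77 ± 0.38 against Angptl4 at -0.45 ± 0.18 and Cpt1a, which brings fatty acids into mitochondria, at -0.38 ± 0.07. Ebp, at 0.61 ± 0.24, was the 1 changed gene of 24 in cholesterol synthesis, also adjusted over the list alone. Among 17 bile acid genes 2 were higher and 3 lower (4 and 4 adjusted over the list alone): Cyp8b1 was at 0.33 ± 0.18 and Slc27a5 at 0.19 ± 0.06, and Cyp7b1 was at -0.98 ± 0.62 and Abcc2 at -0.35 ± 0.10. Of 24 xenobiotic genes Cyp2b9 was higher, on 1 of its 2 probes, and Cyp3a25 at -0.46 ± 0.28 and Cyp1a2 at -0.42 ± 0.22 were lower (2 higher and 2 lower adjusted over the list alone). Cyp3a25 turned to 0.0055 with median centring, and Slc27a5 to -0.04 with Agilent's processed signals. In the gluconeogenesis and insulin list 5 of 18 were higher and 3 lower (6 and 3 adjusted over the list alone). Fbp1 at 0.67 ± 0.10 and Pklr at 0.59 ± 0.33 were higher, and the transcription factor Foxo1 at -0.60 ± 0.05 and the insulin receptor gene Insr at -0.46 ± 0.09 were lower.

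Of 25 p53 and DNA damage genes 2 were higher, Gadd45g and Ccng1 (0.27 ± 0.07), and 2 were lower, Gadd45a (-0.69 ± 0.42) and Gadd45b (-0.27 ± 0.14), with 4 and 4 adjusted over the list alone. In the cell cycle list 4 of 24 were higher and 0 lower, also adjusted over the list alone, with Rrm2 at 0.43 ± 0.08 and Pcna at 0.22 ± 0.09. Hspe1, at 0.27 ± 0.14, was the 1 changed gene of 14 heat shock genes, also adjusted over the list alone. Of 25 interferon genes 2 were higher, Oasl1 at 0.46 ± 0.07 and Tap1 at 0.25 ± 0.12, also adjusted over the list alone. Among 20 clock genes 2 were higher, Noct at 0.39 ± 0.21 and Arntl at 0.20 ± 0.09, and 3 were lower, led by Bhlhe40 at -0.61 ± 0.31 and Tef at -0.37 ± 0.06 (3 and 6 adjusted over the list alone). Of 16 metal handling genes 5 were higher and 1 lower (5 and 2 adjusted over the list alone), with the ferritin gene Fth1 at 0.68 ± 0.10, Slc30a10 at 0.43 ± 0.22 and Id1 at -0.72 ± 0.40. In this list camera's direction was up and the median log2 ratio 0.06, but the mean was -0.08. Of 25 ribosomal protein genes 7 were higher and 0 lower (8 and 2 adjusted over the list alone), with Rpl5 at 0.34 ± 0.09 and Rps18 at 0.27 ± 0.09. Of 16 male-biased genes 2 were lower, Cyp7b1 and C8b at -0.52 ± 0.34, and 0 were higher (2 and 2 adjusted over the list alone). Of 19 female-biased genes Cyp2b9 was the 1 that was higher, also adjusted over the list alone, and its second probe did not pass (adjusted p = 0.291 over all probes). Signs also differed in lists that did not pass: camera pointed down in the vitamin C list (median -0.01, mean 0.10), the xenobiotic list (median -0.02, mean 0.01), the p53 list (median 0.03, mean 0.02) and the T and NK cell list (median 0.01, mean -0.02), and up in the male-biased list (median 0.05, mean -0.06).

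None of the 13 cell type marker lists passed camera in limma, where 1 had an unadjusted p under 0.05 and fry's one-way test also called 0. That list was the sinusoidal endothelial markers (adjusted p = 0.0839), with 2 of 12 members lower, Clec4g at -0.35 ± 0.20 and Kdr at -0.24 ± 0.09, and 4 lower when adjusted over the list alone. The other Clec4g probes gave 0.04 and 0.11, and with the mean of a gene's probes the list passed at the preset correlation (adjusted p = 0.0256; adjusted p = 0.882 with an estimated correlation). Among 12 hepatocyte markers 4 were higher and 1 lower, also adjusted over the list alone: albumin, Alb, was at 0.85 ± 0.21, Apoa2 at 0.84 ± 0.18 and the transcription factor Hnf4a at -0.25 ± 0.10 (list adjusted p = 0.331). Of 11 cholangiocyte markers Spp1 at -0.63 ± 0.32 and Sox9 at -0.58 ± 0.37 were among 3 lower, and Pkhd1 at 0.23 ± 0.07 was higher (1 higher and 4 lower adjusted over the list alone); with the mean of its probes Pkhd1 turned to -0.03. Of 12 stellate cell markers Ecm1 was lower at -0.32 ± 0.21, which turned to 0.024 with median centring, and 0 passed over the list alone. Cfd was the 1 higher gene of 11 adipocyte markers, Ctrb1 at 0.19 ± 0.08 that of 11 pancreatic acinar markers, and Atp2a1 at -0.26 ± 0.15 the 1 lower gene of 11 muscle markers; adjusted over the list alone these lists had 1, 3 and 1 higher and 0, 1 and 1 lower. Gzmb was lower at -0.17 ± 0.03 among 12 T and NK cell markers, and of 10 B cell markers Ighm was higher at 0.20 ± 0.04 and Cd79b lower at -0.23 ± 0.04; adjusted over the list alone 0 T and NK cell markers passed, and 3 B cell markers were higher and 1 lower. In the Kupffer cell, neutrophil, erythroid and intestine lists 0 members passed on the probe that stands for the gene. Adgre1 had 0.19 ± 0.34 and Vsig4 0.18 ± 0.33, S100a9 -0.44 ± 0.36 and Elane 0.11 ± 0.08, Epb42 0.06 ± 0.06, and Lgals4 -0.38 ± 0.37 and Fabp2 0.28 ± 0.30. The second probe of Fabp2 gave 0.48 ± 0.33 and passed (limma adjusted p = 0.0414 over all probes). Those of Adgre1, at -0.03 ± 0.10, and Lgals4, at -0.37 ± 0.34, did not pass.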

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

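All tests in this part were chosen after the results were seen, except that of the other probes of genes near Wrn and the count of sign patterns. The genes of that probe test came from a window chosen after the cluster near Wrn was seen. Of 106 named genes, 1 had 1 array far from the other 3, where about 5.3 would be expected by chance: Tmlhe, whose ratio on array 2 was 0.41 (gap over range 0.860). Array 1 stood apart in its quality measures. Its share of probes well above background was lowest in the mutant channel, at 82.5% (gap over range 0.907), and in the wild-type channel, at 84.2% (0.905). Its share of outlier spots was 0.673% (0.881) and its median coefficient of variation in green 27.3% (0.883), both the highest. Array 2 had the highest median green intensity, at 661.5 (0.866).

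Genes changed by 1.5-fold or more clustered on 1 side of Wrn on chromosome 8, from Saraf at 11 to Frg1 at 43 tested genes away. In the gene order of GRCm38.p6, 8 of the 100 nearest tested genes were called (Saraf, Eri1, Cnot7, Mtmr7, Slc7a2, Fgl1, Pcm1 and Frg1), all on 1 side of Wrn, against 5 in the fullest window elsewhere, and random placement gave a permutation p of 1e-05, the smallest that 100000 draws can give. The wild-type level of Fgl1, like that of the Saa genes, was highest on array 4, at 17.1 against 14.3, 14.9 and 14.8. The window was chosen after the cluster was seen. With 25 genes on each side 2 were called (permutation p = 0.0641), and 1267 of 19502 windows elsewhere held as many. With 100 on each side 9 were called (permutation p = 1e-05), against 7 in the fullest window elsewhere. Bases that differ between the mutant's DNA and the probes may account for part of the cluster: of 7 other probes of these genes 3, or 42.9%, moved the same way past the threshold, between the limits set beforehand, and elsewhere the share was 51.2%. The 7 probes belong to 5 genes, so they are not independent, and the 3 are probes of Mtmr7 and Pcm1. Saraf, Slc7a2 and Frg1 had no other kept probe and could not be checked in this way. With 50 genes on each side, 0 of 19352 windows elsewhere held as many called genes. That count bears on random placement and cannot separate genotype from vitamin C. For the cluster and for each single gene an effect of genotype or of vitamin C stays open because the design varies them together. No other biological explanation was tested.

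Saa1, Saa2 and Saa3 were lower on every array, and the rest of the acute phase list was lower mainly on array 4. A response in the wild-type animal of array 4 alone would leave the Saa genes near 0 on the other arrays, but their mean was at most -0.97 on each. A constant dye bias alone would give the same ratio on every array, but the Saa mean ran from -0.97 on array 1 to -4.18 on array 4. That spread argues against it as the whole cause. A constant part of the Saa ratios cannot be told apart from the group difference, because 0 arrays had the dyes swapped. The other 23 members had a mean log2 ratio of -0.32 over 4 arrays and -0.07 without array 4, where camera in limma gave an unadjusted p = 0.145 (adjusted p = 0.309 over the pathway lists, against 0.0350 with array 4). On array 4 these members stood above the other arrays by a mean of 1.29 log2 units in the wild-type animal and of 0.29 in the mutant, where Lcn2 stood 3.77 and Orm3 2.04 above, so whether that wild-type animal alone responded stays open. An effect of genotype or of vitamin C also stays open, as does a difference in the health of the animals of either genotype.

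Most of the changed genes had small changes. After a correction for the base composition of the probes 3569 genes were changed, against 3189 before, so that trend was not the whole cause. A dye bias of single probes cannot be told apart from the group difference, because 0 arrays had the dyes swapped. The 4 arrays allow 8 sign patterns, too few for a share under 0.05: 1 of 8, the real one, gave 3189 changed genes and the highest of the others 0, and at 1.5-fold or more 1 of 8 gave 193 and the highest other 0.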

How the results depend on the processing

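The naming alternatives, the base composition correction and the mean of a gene's probes for lists were chosen after seeing the data. Slide and scan date were not run as a block because all arrays share them. The 24 largest changes were chosen for 1 sign on all 4 arrays, so leaving out or weighting arrays could not turn their sign. All 24 also kept it in the other alternatives run. Among those, Aquantile normalization, the intensity trend with robust moderation and the fit without pairing of channels could not turn a sign either. Of the 24 genes 7 stayed past the threshold whichever array was left out, and 3 did so in every alternative. Of all 96 named genes past the threshold, 7 stayed past it in every alternative: Slc7a2, Dusp1, Saraf, Fbp1, Foxo1, Alb and Apoa2. Only Foxo1 among these 7 had another probe, so averaging a gene's probes could not change the others. Slc7a2 and Saraf are among the called genes near Wrn. Fbp1, Alb and Apoa2 were bright, with mean log2 intensities of 17.7, 18.0 and 17.6. Their log2 ratios reached 1.32, 1.53 and 1.48 in single alternatives, against 0.67, 0.85 and 0.84. No alternative separates a dye bias from the group difference. Leaving out 1 array gave 49 to 1340 changed genes, 44 to 205 at 1.5-fold or more, 0 to 2 of the 5 Wrn and vitamin C genes, 4 to 8 pathway lists and 0 to 1 marker lists. Fewer arrays leave fewer degrees of freedom. Without the replicate block, with the pairing of channels not modelled, 24 genes were changed, all by 1.5-fold or more, and 0 of the 5 genes. Agilent's processed signals gave 811 changed genes and 1 of the 5. Median centring gave 4923 changed genes, 480 at 1.5-fold or more, 1 of the 5 genes and 1 marker list. The intensity trend with robust moderation gave 1 of the 5, and its split was 2652 higher and 983 lower. At an unadjusted p under 0.01 with 1.5-fold, 200 genes passed, and at 0.001 with 1.5-fold, 144. Estimated correlation called 0 pathway lists, fry's one-way test 0, and its mixed test 22 pathway and 6 marker lists. The mean of a gene's probes called 7 pathway lists and 1 marker list. With every probe tested on its own 4480 genes had a changed probe, 2289 a higher one and 2267 a lower one, against 1734 and 1455. Some genes are in both of these counts. Other totals stayed within 1.5 times. Values that changed sign were, with Agilent's processed signals, Wrn (-0.049), Slc27a5 (-0.037) and Epb42 (-0.036), and with median centring Gulo (0.26), Cyp3a25 (0.0055), Ndufv1 (0.13), Ecm1 (0.024) and the complement list (adjusted p = 0.104). Pkhd1 turned to -0.028 with the mean of probes, and Wrn to -0.0012 with array weights and to between -0.0076 and 0.0083 with 1 array left out. For these the cause was not tested. Array 1 had the smallest share of probes well above background, but its array weight was 1.16, against 0.83, 0.87 and 1.19 on arrays 2, 3 and 4.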

Other observations

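The test in this part was chosen after the result was seen. Dusp1 was among the largest decreases, and it belongs to the immediate early genes, which respond within minutes to growth factors and stress. Of 28 other measured members of a list written after the named genes were known, 10 were lower, 3 higher and 15 not past the test; adjusted over the list alone, 13 were lower and 5 higher. Dusp6 was at -1.04 ± 0.29, Junb at -0.88 ± 0.46 and Fos at -0.75 ± 0.40 (SD, n = 4), whereas Myc was higher at 0.94 ± 0.41. A fall of the group without Dusp1 is a hypothesis: camera gave an unadjusted p = 0.000245 with the preset correlation, but an unadjusted p = 0.0810 with an estimated correlation, so the question stays open.

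The 2 probes of Wrn that overlap share 51 bases and differ by 1 substitution, G23A, with position 1 at the first shared base and the base of the probe at 0.00 ± 0.02 written first. The other probe gave 0.41 ± 0.10.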
